A study of Mus musculus with 4 samples.

How the data were processed

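The 4 samples were brain sections of mice 6 to 8 weeks old, 2 labelled WT and 2 labelled Sema6d-/-, each measured on a Visium slide. The files deposited for each section hold raw UMI counts per gene and spot, without normalisation, once for all spots of the capture area and once for the spots over tissue. The spot positions deposited by the authors hold other values: a flag of 0 or 1 for a spot over tissue and its array row and column. The processing notes name Space Ranger 1.3.0 and the mm10 build; the annotation is not stated. Counts were whole numbers, and the tissue matrices matched the full ones at all shared features and spots. The tissue matrices held 19465 of 32589 features. No UMI fell on the 13 mitochondrial or 97 ribosomal protein features of the full matrices, so those lists were not measured. Whether the slides used probes or 3' capture is not stated, and 3' capture would have left UMIs on these genes, so their absence argues against it unless they were removed before deposit. Of the 13124 features outside the tissue matrices, only 898 to 1152 per section held any UMI, which argues against 3' capture too. Sheets of the submission form were not used here.

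Section totals ranged from 33797289 to 125996145 UMIs. The smallest section held 16590 genes with a UMI and the largest 17998. Counting error between the 2 WT sections was exceeded 15.2 times in variance (chi-squared per degree of freedom) and between the 2 sections labelled Sema6d-/- 8.58 times, so none duplicates another. Between labels the ratio was 49.6 to 78.6. Gene positions came from a reference table of assembly GRCm38.p6, the primary sequence of mm10, in which 15248 of 15304 tested genes were found. Positions of the named genes were looked up by gene symbol or synonym.

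Tests, gene lists, markers, the rule for named genes and the alternatives were fixed before the data were examined. The section was the replicate, and spots were summed. Spots were grouped into regions with scanpy 1.11.5 and scikit-learn 1.9.0: counts per 10000 were log-transformed, 2000 variable genes were ranked with the section as batch, values were centred and scaled within each section, and 30 principal components gave a graph of 15 nearest neighbours. Sema6d, Xist, Y-linked, mitochondrial and haemoglobin genes were left out of the variable genes. The graph was partitioned with leidenalg 0.10.2 at resolution 1 and seed 1. A region was tested if every section held at least 20 of its spots. Regions are named by their leading genes, and marker lists of brain areas were compared with them.

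Whole-section sums and each region's sums were tested in R 4.3.3 with edgeR 4.0.16 quasi-likelihood (robust, TMM factors, filterByExpr by genotype). Region-standardised values were the equal-weight mean over regions of log2 CPM (prior count 2) and were tested with limma 3.58.1 (trend, robust). The region by genotype test set, per section, a region's log2 CPM against the mean of the other regions, also in limma. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, within each region for regional tests. Of 25 gene lists fixed beforehand, 22 had at least 5 tested members and were tested with camera (preset correlation 0.01), with an estimated correlation beside it. With the estimate, camera rests on the residual degrees of freedom of 4 sections, so it has little power here. The lists were semaphorins, plexins and neuropilins; other axon guidance and adhesion; GABAergic and glutamatergic neurons; presynaptic release, the postsynaptic density, and GABA receptors; immediate early genes; neuropeptides; monoamine receptors; myelin, oligodendrocyte precursors, astrocytes, microglia, endothelium, meninges, choroid plexus and blood; the mitochondrial genome, oxidative phosphorylation and the ribosome; and heat shock, interferon, cholesterol, and glucocorticoid and circadian genes. Some genes stand in more than 1 list, such as Enpp2, Olig1, Olig2, Arc and Nlgn2. Shares of spots were compared with a 2-sided exact permutation test.

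Named genes were up to 10 higher and 10 lower with the largest log2 change among those that passed with a mean of at least 5 CPM in the higher group, and list members that passed. In the amygdala marker region, the tested region with the highest mean z of basolateral amygdala markers in the WT sections, they were the up to 10 per direction of smallest p, filled to 5 with genes that did not pass. In each other region they were the up to 3 per direction of smallest p. Sema6d and Plxna1 to Plxna4 were always given, and gene models without a proper symbol were passed over.

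The tests were tried on simulated data with known changes in 200 genes. For whole sections, 20 of 178 calls were false (11.2%), and in the amygdala marker region 9 of 97 (9.28%), both above the 5% the threshold allows. For region-standardised values the share was 1.60%, with the regions drawn independently, so deviations shared by all regions of a section were not simulated. In the amygdala marker region, the only region simulated for it, the region by genotype test found none of the simulated 2-fold changes and 48.7% of the 4-fold ones.

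Alternatives were RLE factors, DESeq2 1.42.0, no filter, counts thinned to the lowest total, spots of at least 1000 UMIs, a prior count of 0.5, regions weighted by size, equal numbers of spots per region, resolutions 0.5 and 1.5, clustering without centring by section, spots with at least 4 neighbours of their region, regions of at least 50 spots, the replicate number as a block, fry, and each section left out in turn. Confidence intervals are at 95% and exact, except those of medians, which are bootstrap intervals over genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9 were used.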

Results

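Spatial gene expression was measured on Visium slides, on which each spot over a tissue section captures RNA, or probes bound to it, under its own barcode. The 4 brain sections came from mice 6 to 8 weeks old, 2 labelled WT and 2 labelled Sema6d-/-, with the strain given as C57BL6/J for all. The WT sections held 1807 and 2174 spots over tissue, with 120281973 and 125996145 unique molecular identifiers (UMIs). The sections labelled Sema6d-/- held 2101 and 2296 spots, with 33797289 and 51317158 UMIs. The median spot held 61446 and 53738.5 UMIs in the WT sections and 15148 and 21288 in the others. Depth thus separated the genotypes completely, and no batch was labelled, so batch and genotype cannot be told apart in any comparison. All p-values measure only the spread between these sections.

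The sections covered cortex, striatum, thalamus, hypothalamus and hippocampus, as marker genes showed. Spots fell into 33 regions, of which 25 held enough spots in every section to be tested, and each is called here by its leading gene. The Adora2a region, led by the striatal adenosine receptor gene, had 8 of 8 measured striatal markers more than 2-fold above the other regions. The Dsp region had 6 of 6 dentate gyrus markers above that level. The Gbx2 region had 8 of 8 thalamic markers above it, and the Avp region 9 of 11 hypothalamic ones. The Cldn11 region had all 8 fibre tract markers above it, and the Myoc region all 6 meningeal ones.

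**Figure D1:**
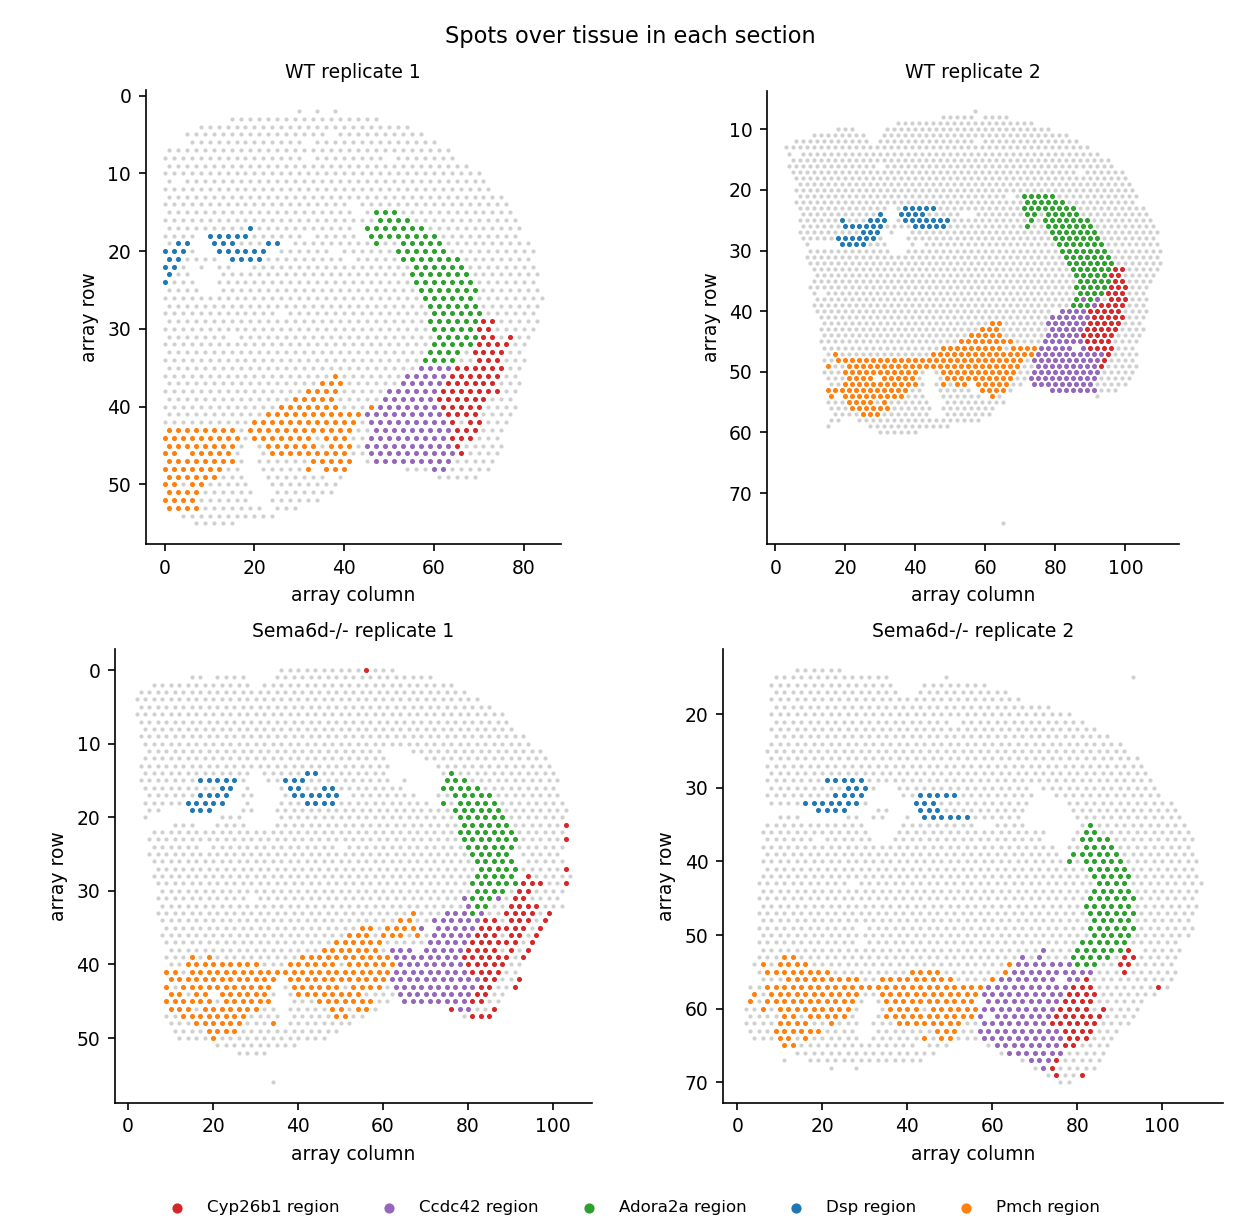
Spots over tissue in the 4 sections by array column and array row (array units), with 5 regions coloured by their leading gene and all other spots in grey. The Adora2a, Dsp, Pmch, Ccdc42 and Cyp26b1 regions were present in all 4 sections.

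Sema6d, the targeted gene, encodes a transmembrane semaphorin that guides axons and binds plexins. Its signal was higher, not lower, in the sections labelled Sema6d-/-, which goes against the label. Sema6d (ENSMUSG00000027200, chromosome 2, 124089943 to 124667789 on mm10) stood at 139 ± 10.3 CPM in the sections labelled WT and 301 ± 0.0165 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), where CPM are counts per 1000000 UMIs of a section or region. It had a log2 change of 1.11, SE 0.0606, adjusted p = 2.02e-05, and both sections labelled Sema6d-/- lay above both WT sections. It was higher in 24 of 25 regions, with log2 changes from 0.87 to 1.496. The region without a call was the Cyp26b1 region, with 0.87 and adjusted p = 0.0956. Neither the deleted part of the gene nor the measured part of its transcript is given, nor whether probes or 3' capture were used, and a signal from outside the deletion checks nothing about the genotype. Directions below are therefore those of the labels, and no difference below is tied to a loss of Sema6d transcript.

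Plexin-A1, the best known Sema6d receptor, was also higher. Plxna1 had a log2 change of 0.76, SE 0.0545, adjusted p = 1.09e-04. Plxna2, encoding another class A plexin, had a log2 change of 0.58, SE 0.0699, adjusted p = 7.62e-04. Plxna3 (0.11, adjusted p = 0.183) and Plxna4 (0.19, adjusted p = 0.0576) did not pass. In the WT sections Sema6d was highest in the Eps8l2 region, at 204 ± 15.5 CPM (SD, n = 2), against 571 ± 17.3 CPM in the sections labelled Sema6d-/-. It was lowest in the Vip region, at 74.3 ± 0.843 CPM. Plxna1 was highest in the Nr5a1 region (94.4 ± 16.6 CPM) and lowest in the Adora2a region (27.1 ± 3.96 CPM). Plxna2 ranged from 38.4 ± 1.54 CPM in the Fgf10 region to 111 ± 6.53 CPM in the Plxnd1 region. Plxna3 peaked in the Nr5a1 region at 53.7 ± 10.1 CPM, and Plxna4 in the Dsp region at 404 ± 24.7 CPM. By region, Plxna1 was called higher in 17, Plxna2 in 13 and Plxna4 in 4 (the Eps8l2, Vip, Adam33 and Dsp regions). The plexin-A1 partners Trem2 and Tyrobp stayed low in the WT sections, at most 18.9 CPM in the Lhx8 region and 19.0 CPM in the Cldn11 region. Kdr, a vascular growth factor receptor gene, was 7.12-fold lower (95% exact interval 2.32 to 35.6) in the Adam33 region, on 3 UMIs in the sections labelled Sema6d-/- (adjusted p = 9.55e-04). Kdr was tested in 18 regions, this was its only call, and its log2 changes ran from -2.75 to 0.81.

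**Figure D2:**
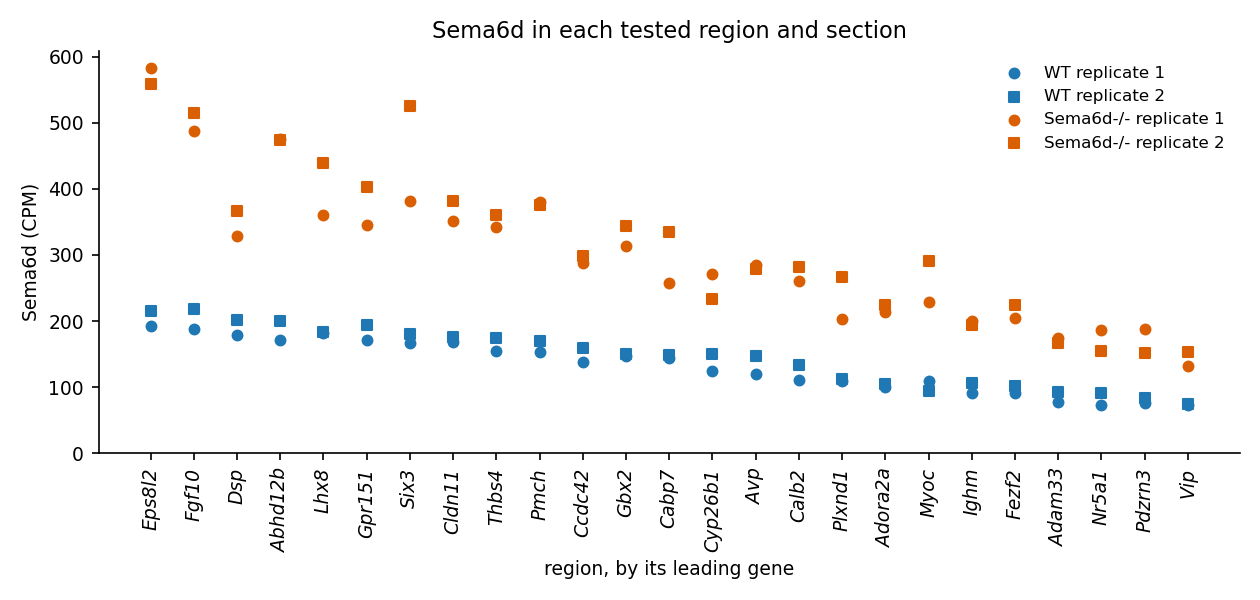
Sema6d (CPM) in each tested region, ordered by the WT mean, with 1 point per section (blue WT, orange Sema6d-/-). Whole-section values were 131 and 146 CPM in WT and 301 and 301 CPM in the sections labelled Sema6d-/-.

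Over whole sections, 20 genes stood out by size. Section plane and cut anatomy were not controlled, so this compares 2 and 2 sections and not the brains of the genotypes. Higher in the sections labelled Sema6d-/- were Pla2g4e, a phospholipase gene (2.97 on the log2 scale), and Serpina3n, a secreted protease inhibitor of reactive astrocytes (2.29). Glo1, which detoxifies methylglyoxal, was higher by 1.93, Masp2 of the complement lectin pathway by 3.06, and Avp, the vasopressin gene, by 1.77. Lower were Txlna, a syntaxin-binding taxilin (-5.01), Pigv, an enzyme of GPI anchor synthesis (-7.62), Lmo3, a LIM-only transcription cofactor (-2.97), and Pmch, the melanin-concentrating hormone precursor (-1.72). Cort, which encodes the interneuron peptide cortistatin, had 2503 UMIs in the WT sections and 3 in the others, 288-fold lower (95% exact interval 98.6 to 1399). Such intervals cover counting error only.

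In measured levels, Pla2g4e (ENSMUSG00000050211, chromosome 2, 120166412 to 120245630) had 8.75 ± 1.36e-04 CPM in the sections labelled WT and 68.9 ± 0.626 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), with SE 0.0585 and adjusted p = 3.63e-08. Glo1 (ENSMUSG00000024026, chromosome 17, 30592861 to 30612659) had 58.6 ± 2.15 CPM in the sections labelled WT and 224 ± 12.2 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), with SE 0.0605 and adjusted p = 3.88e-07. Serpina3n (ENSMUSG00000021091, chromosome 12, 104406646 to 104414334) had 13.4 ± 0.156 CPM in the sections labelled WT and 65.9 ± 1.89 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), with adjusted p = 7.37e-08. Txlna (ENSMUSG00000053841, chromosome 4, 129626077 to 129641065) had 41.5 ± 1.41 CPM in the sections labelled WT and 1.34 ± 0.407 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), with SE 0.128 and adjusted p = 7.37e-08. Lmo3 (ENSMUSG00000030226, chromosome 6, 138362918 to 138582206) had 156 ± 33.5 CPM in the sections labelled WT and 19.8 ± 3.39 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), with SE 0.153 and adjusted p = 1.47e-05. Pmch (ENSMUSG00000035383, chromosome 10, 88091072 to 88092374) had 1315 ± 125 CPM in the sections labelled WT and 402 ± 125 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), with adjusted p = 0.00374. The other higher genes were Card10 (1.81), Mid1 (1.80), a ubiquitin ligase gene, the mitochondrial transhydrogenase gene Nnt (ENSMUSG00000025453, 1.60), the histone gene Hist4h4 (1.56) and Hmga1b (8.16). Hmga1b nearly copies Hmga1 and had 4 and 8 UMIs in the WT sections, so its value is uncertain. The other lower genes were Smco3 (-3.25), Pde6h (-2.44), Spg11, mutated in hereditary spastic paraplegia (-1.90), Nrip2 (-1.31) and Tex52 (-1.23). For all 20, both sections of a label lay beyond both of the other.

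**Figure D3:**
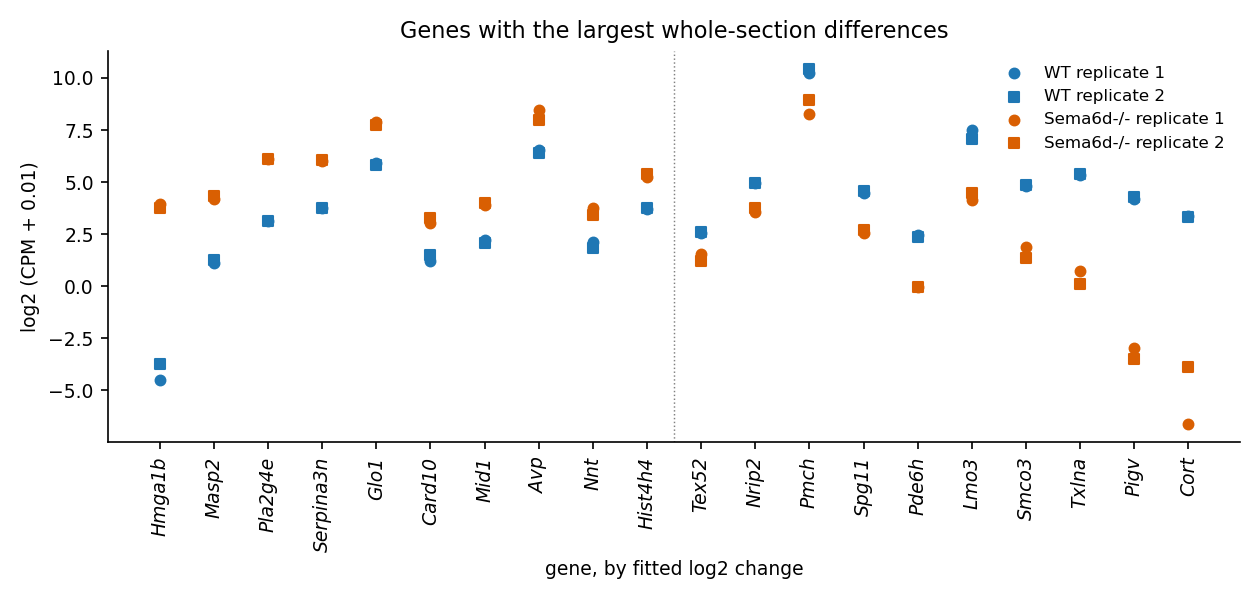
The 20 named genes of the whole-section comparison as log2 (CPM + 0.01), with 1 point per section (blue WT, orange Sema6d-/-), ordered by fitted log2 change. Higher genes stand left of the dotted line and lower genes right of it, and the sections of each label lie together.

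Of 15304 genes tested, 2671 were higher and 2516 lower in the sections labelled Sema6d-/- (33.9% of the genes), with a median change of 1.25-fold among those called. At least 2-fold changes, a limit chosen after the data were seen, numbered 89 higher and 110 lower. Without WT replicate 2, 1778 genes were higher and 1629 lower, and without WT replicate 1, 1623 were lower. On simulated changes, 11.2% of this test's calls were false, above the 5% the threshold allows.

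Over whole sections, several genes of excitatory neurons and of neuronal activity were higher in the sections labelled Sema6d-/-, and the calls of their lists were lost with an estimated correlation. Of the glutamatergic neuron list, 13 higher of 18 tested (14 higher adjusted over the list alone) passed, among them Camk2a (0.77), Nrgn (0.63), Cux2 (0.63) and Tbr1 (0.47), given as log2 changes, which encode a synaptic kinase, neurogranin and cortical transcription factors, camera adjusted p = 2.11e-06, and adjusted p = 0.596 with an estimated correlation. Of the immediate early genes, switched on by neuronal activity, 11 higher and 1 lower of 20 tested (12 higher and 1 lower adjusted over the list alone) passed, with Egr3 (0.78), Nr4a1 (0.48) and Dusp1 (0.52) higher and Fos (-0.37) lower, camera adjusted p = 0.00127, and adjusted p = 0.596 with an estimated correlation. In the postsynaptic list, 12 higher and 3 lower of 29 tested (13 higher and 3 lower adjusted over the list alone) passed, with Grm5 (0.56), Dlgap1 (0.49) and Homer1 (0.47) higher and Dlg2 (-0.21) lower, camera adjusted p = 0.0423, and adjusted p = 0.596 with an estimated correlation. That call was lost without replicate 2 of the sections labelled Sema6d-/- (adjusted p = 0.0708). The presynaptic release list was split, 8 higher and 7 lower of 25 tested (9 higher and 8 lower adjusted over the list alone), with Syt1 (0.63) and Syn1 (0.46) against Vamp1 (-0.35) and Nrxn3 (-0.32), camera adjusted p = 0.803. GABAergic neuron genes gave 9 higher and 2 lower of 25 tested (9 higher and 2 lower adjusted over the list alone), with Dlx2 (0.64) higher and Prox1 (-0.50) and Pvalb (-0.42) lower, camera adjusted p = 0.328. The GABA receptor list gave 5 higher and 2 lower of 19 tested (5 higher and 3 lower adjusted over the list alone), with the receptor subunits Gabra2 (1.01) and Gabrb2 (0.59) higher and Gabrg1 (-0.35) lower, camera adjusted p = 0.321.

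Most myelin genes were lower, as were 7 of the choroid plexus and ependyma genes, while most members of the astrocyte, precursor and vascular lists did not pass. Of the myelin and oligodendrocyte list, 17 lower of 22 tested (19 lower adjusted over the list alone) passed, including Opalin (-0.88), Sox10 (-0.57), Mobp (-0.40) and Mbp (-0.32), camera adjusted p = 2.05e-07, and adjusted p = 0.634 with an estimated correlation. Choroid plexus and ependyma gave 1 higher and 7 lower of 14 tested (1 higher and 8 lower adjusted over the list alone), with Folr1 (-0.91) and Ttr (-0.62) lower and the cilia regulator Foxj1 (0.50) higher, camera adjusted p = 0.0205, and adjusted p = 0.699 with an estimated correlation. Without replicate 2 of the sections labelled Sema6d-/- the choroid plexus call was lost (median from -0.32 to -0.18, adjusted p = 0.146), and the myelin median went from -0.35 to -0.22 with the call kept. Oligodendrocyte precursors gave 3 lower of 10 tested (3 lower adjusted over the list alone), led by C1ql1 (-0.40), camera adjusted p = 0.0764. Astrocytes gave 3 lower of 15 tested (3 lower adjusted over the list alone), S100b (-0.65), Agt (-0.46) and Slc4a4 (-0.18), camera adjusted p = 0.142. Microglia and macrophages were split, 4 higher and 4 lower of 16 tested (4 higher and 4 lower adjusted over the list alone), with Tmem119 (0.53) and Cx3cr1 (0.29) against Trem2 (-0.44) and Ctss (-0.37), camera adjusted p = 0.714. Endothelial and mural cells gave 3 higher and 1 lower of 16 tested (2 higher and 1 lower adjusted over the list alone), with Flt1 (0.24) higher and Vtn (-0.25) lower, camera adjusted p = 0.956; their median was -0.06, their mean 0.04 and the test's direction lower. Meninges and fibroblasts gave 1 higher and 4 lower of 12 tested (1 higher and 4 lower adjusted over the list alone), with Slc6a13 (-0.42) lower and Slc47a1 (0.42) higher, camera adjusted p = 0.142. Only 4 blood genes could be tested, too few for camera: Hba-a2 (0.97), Hbb-bs (3.86) and Hbb-bt (2.56) were higher from under 2 CPM in WT, and Bpgm (-0.17) was lower.

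Guidance and metabolic lists gave a mixed picture. Semaphorins, plexins and neuropilins were split, 9 higher and 9 lower of 30 tested (11 higher and 11 lower adjusted over the list alone), with Sema4a (0.61) and Plxnd1 (0.36) against Sema4g (-0.38) and Nrp2 (-0.30), camera adjusted p = 0.521. Other axon guidance and adhesion genes gave 6 higher and 6 lower of 34 tested (6 higher and 6 lower adjusted over the list alone), with Robo3 (0.42) and Efna5 (0.34) against Cntn4 (-0.39) and Unc5b (-0.35), camera adjusted p = 0.957. Nuclear genes of oxidative phosphorylation gave 3 higher and 14 lower of 27 tested (4 higher and 15 lower adjusted over the list alone), with Ndufa2 (-0.54), Ndufa13 (-0.54) and Cox6c (-0.47) lower and Ndufa7 (0.44) higher, camera adjusted p = 0.00468, and adjusted p = 0.596 with an estimated correlation. Glucocorticoid and circadian genes gave 8 higher and 2 lower of 17 tested (8 higher and 2 lower adjusted over the list alone), with the clock genes Cry2 (0.73), Nr1d1 (0.66) and Dbp (0.50) higher and the glucocorticoid target Tsc22d3 (-0.41) lower, camera adjusted p = 0.0205, and adjusted p = 0.596 with an estimated correlation. Neuropeptides gave 4 higher and 5 lower of 21 tested (4 higher and 5 lower adjusted over the list alone), with Cartpt (-0.97) and Gal (-0.91) lower and Grp (0.91) higher, camera adjusted p = 0.492. Monoamine receptors and synthesis gave 4 higher and 6 lower of 23 tested (4 higher and 6 lower adjusted over the list alone), with Th (-0.79) and Drd2 (-0.61) lower and Adra1a (0.62) higher, camera adjusted p = 0.492. Heat shock and unfolded protein genes gave 2 higher and 8 lower of 18 tested (3 higher and 8 lower adjusted over the list alone), with Hsp90b1 (-0.33) lower and Hspa1b (0.51) higher, camera adjusted p = 0.291. Interferon and antigen presentation gave 2 higher and 7 lower of 18 tested (2 higher and 7 lower adjusted over the list alone), with Oasl2 (-0.60) and Ifit2 (-0.46) lower and Irf7 (0.80) higher, camera adjusted p = 0.0586. Cholesterol synthesis gave 1 higher and 4 lower of 15 tested (1 higher and 5 lower adjusted over the list alone), with Sqle (-0.43) lower, camera adjusted p = 0.679. Genes of the mitochondrial genome and the cytosolic ribosome had no UMIs. No list call held with an estimated correlation. With fry the immediate early (adjusted p = 0.0930), myelin (0.128) and choroid plexus (0.222) calls were lost, and the semaphorin (0.0420), heat shock (0.0457) and interferon (0.0457) lists passed. Fry asks whether a list changed at all, and camera whether it changed more than other genes.

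**Figure D4:**
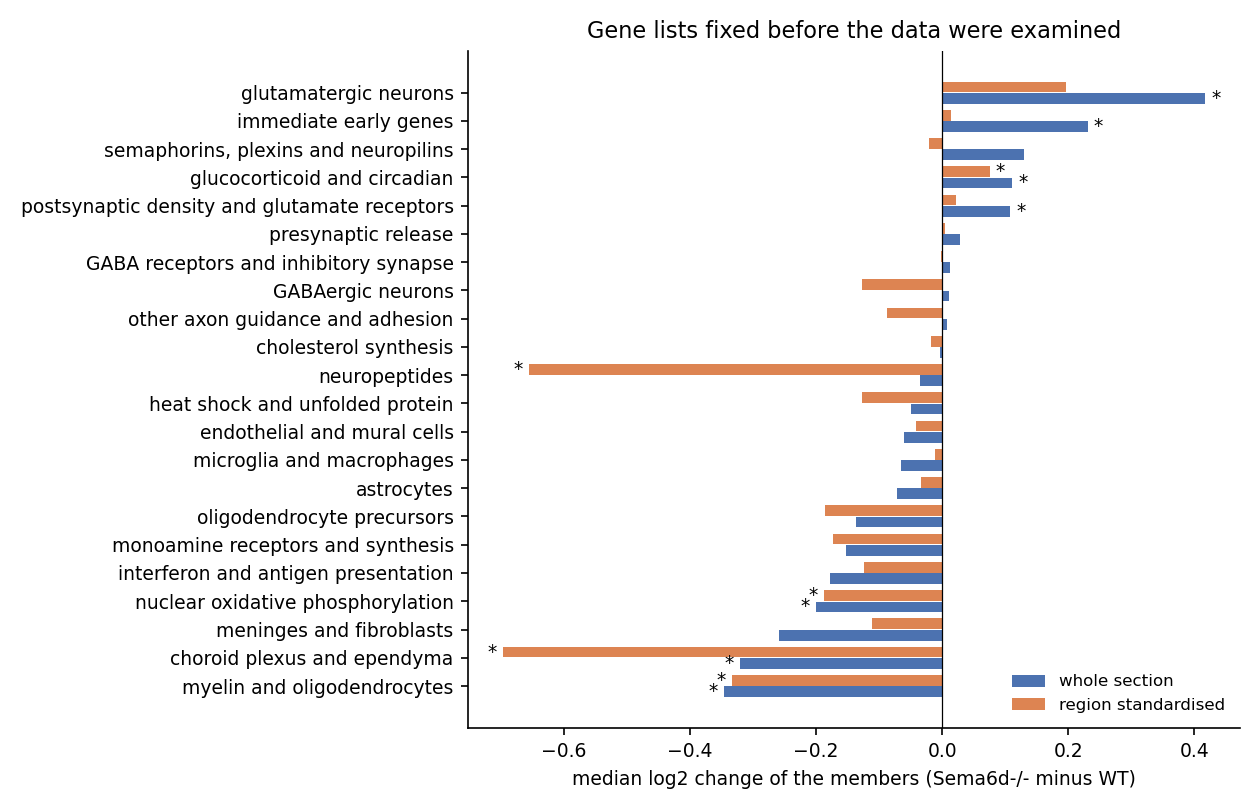
Median log2 change (Sema6d-/- minus WT) of the members of each of 22 tested gene lists, over whole sections (blue) and region standardised (orange), with an asterisk where camera passed its threshold. The glutamatergic list had the median 0.42 and the myelin list -0.35 over whole sections.

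With every region weighted equally, so that the number of spots per region no longer counts, the largest differences included genes not named over whole sections. Pmch fell by 3.34 on the log2 scale in the sections labelled Sema6d-/- (adjusted p = 0.0497), the oxytocin gene Oxt by 2.03 (4.49e-05) and the galanin gene Gal by 1.79 (8.75e-05). Arhgap36 (-1.75) and Dlk1 (-1.65), a Notch ligand gene imprinted in mice, were lower too. Oxt was not lower over whole sections (0.50), and its direction turned (0.52) when equal numbers of spots per region were summed and tested with edgeR. That setting no longer weights regions equally, so the turn cannot be put down to spot numbers. Avp, higher over whole sections, had -0.86 with every region weighted equally (limma adjusted p = 0.144). Within the region of its highest level, Oxt stood at 0.24, Avp at 1.79, Arhgap36 at 0.19 and Pmch at -0.94 on the log2 scale. Outside it the same genes stood at -2.73, -1.40, -2.78 and -3.39, so their low values on this scale came mainly from regions with little of their transcript. Pla2g4e (2.94), Serpina3n (2.56), Glo1 (1.95), Masp2 (2.73) and Btbd9 (1.14) were higher on this scale as well, as were Hmga1b (4.34), Mid1 (1.55), Hist4h4 (1.495), Nnt (1.41) and Card10 (1.36). Pigv (-4.70), Txlna (-4.55), Lmo3 (-3.25), Smco3 (-2.92) and Spg11 (-1.80) were lower.

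The neuropeptide list was lower on this scale, 10 of 18 members (1 higher and 11 lower adjusted over the list alone), with Cartpt (-1.38), Trh (-1.02) and Penk (-0.72), camera adjusted p = 4.41e-05, and adjusted p = 0.688 with an estimated correlation. In their source regions Avp (1.79), Pomc (0.86), Tac1 (0.64), Oxt (0.24), Penk (0.23) and Adcyap1 (0.04) were not lower. Pmch (-0.94), Hcrt (-1.07) and Cartpt (-0.80) were lower there, and all of these were lower outside. The list call thus does not by itself show a fall where the peptides are made. Penk, for enkephalin, turned (0.0472) when equal numbers of spots were summed over regions, which no longer weights regions equally. Myelin genes were lower in 18 of 22, with Opalin (-0.90), camera adjusted p = 4.96e-07, and adjusted p = 0.771 with an estimated correlation. Of the choroid plexus and ependyma genes, 4 of 7 were lower, with Ccdc153 (-1.04), camera adjusted p = 0.0219, and adjusted p = 0.688 with an estimated correlation. The Ttr and Tmem212 regions, each led by a gene of this list, were too small to be tested. The value thus covers only other regions and says nothing about choroid plexus or ependyma themselves. Of the oxidative phosphorylation genes, 14 of 27 were lower, camera adjusted p = 0.0304, and adjusted p = 0.688 with an estimated correlation. Of the glucocorticoid and circadian genes, 7 of 16 were higher, camera adjusted p = 0.0414, and adjusted p = 0.688 with an estimated correlation. The glutamatergic, immediate early and postsynaptic lists did not pass on this scale (camera adjusted p = 0.119, 0.471 and 0.362), with 3 higher and 2 lower of 18, 3 and 2 of 20, and 9 and 6 of 29. The semaphorin, GABA receptor and cholesterol lists had negative medians here (-0.02, -0.00183 and -0.02) while camera gave them the higher direction. Of 11488 genes tested with limma, 1890 were higher and 2512 lower, and 11 and 34 of them by at least 2-fold. Of the 3801 genes called on both scales, 3800 had the same direction. Without WT replicate 1, 1191 were higher and 1305 lower, and without WT replicate 2, 1258 and 1464.

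The share of spots in each region was compared between the labels. The Vip region, with upper-layer cortical markers, held 1.74% ± 0.511 and 5.84% ± 0.727 of the spots in WT and in the sections labelled Sema6d-/- (SD, n = 2 each). The Fst region, with the same kind of markers, held 5.09% ± 0.864 and 0.154% ± 0.151 and was too small there to test. Together the Vip and Fst regions held 6.83% ± 0.352 and 6.00% ± 0.878, a sum taken after their opposite shares were seen. The Cldn11 fibre tract region held 3.28% ± 0.214 and 1.97% ± 0.295, and the thalamic Gbx2 region 7.36% ± 0.0721 and 5.71% ± 0.607. The striatal Adora2a region held 5.80% ± 0.792 and 4.33% ± 0.207, and the Gpr151 region, with habenular markers, 1.24% ± 0.198 and 2.78% ± 0.850. The Col3a1 region held 0.0507% ± 0.00661 and 1.57% ± 2.02, nearly all of it in replicate 2 of the sections labelled Sema6d-/-. In 11 of 25 tested regions the shares of the labels did not overlap (44%, against 33.3% by chance). With 2 sections against 2, the 2-sided exact permutation p cannot go below 0.333, so no share could be called.

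Within regions, a few genes recurred. Of the 7548 genes called in any region, 618 were higher in some regions and lower in others. Btbd9, Glo1 and Pla2g4e were higher and Pigv and Txlna lower in all 25 tested regions, 5 genes picked out after their values were seen. Among the genes of smallest p in the 24 regions other than the Cyp26b1 region, Glo1 was named in 23 (log2 change 1.47 to 2.46) and Pla2g4e in 16 (2.504 to 3.63). Serpina3n was named in 12 (2.16 to 3.72) and Sema6d in 6 (1.08 to 1.496). On the lower side came Txlna in 18, Lmo3 in 17 (-3.88 to -2.41), Pmch in 7 (-4.65 to -3.36), Smco3 in 5 (-3.68 to -2.62), Pigv in 5 and Pcp4, a calmodulin regulator gene, in 4 (-2.17 to -0.98). Camk2a was named higher in 3 regions (0.73 to 1.10), Padi2, which converts arginine to citrulline, in 3 (2.505 to 2.81), and the orexin gene Hcrt lower in 3 (-4.79 to -1.57). Pmch and Hcrt were named only outside the Pmch region, where both were highest. In the WT sections Pmch stood at 80.6 to 306 CPM in its 7 regions, against 8550 and 10472 CPM in the Pmch region. These calls thus concern regions with little of the transcript. Of the 33 genes so named, 18 were named in 1 region, among them Cd74 of antigen presentation (3.22).

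Over the 288793 gene-by-region tests of edgeR, 16178 were higher and 13732 lower, from 7548 genes. The Ighm region, with layer 6 markers, had the most calls, 1791 higher and 1732 lower, and the Cyp26b1 region the fewest. DESeq2 gave 5666 higher and 3924 lower, and counts thinned to the lowest total gave 10187 and 8959. Without WT replicate 2, 10613 were higher; without WT replicate 1, 8817 were lower, and without replicate 2 of the sections labelled Sema6d-/-, 7979.

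**Figure D5:**
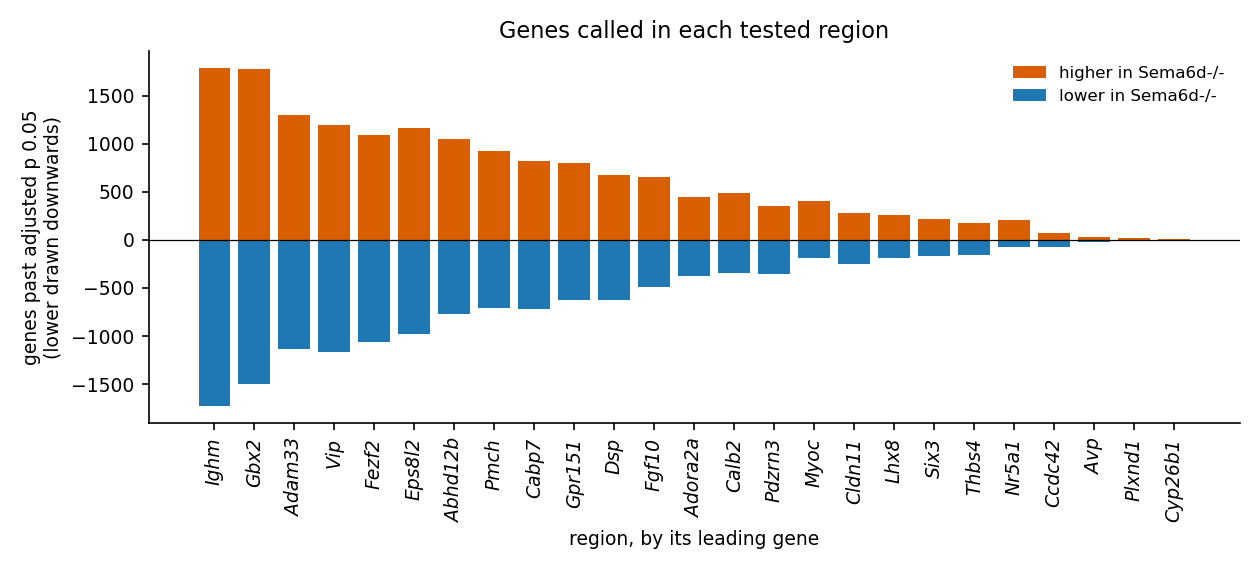
Genes past an adjusted p of 0.05 in each tested region, higher in Sema6d-/- drawn upwards and lower drawn downwards, ordered by their sum. The Ighm region had 1791 and 1732, and the Cyp26b1 region 4 and 8.

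The amygdala was examined on its own, as the analysis plan had set. The Cyp26b1 region, led by Cyp26b1 and Bmp3, carried the basolateral amygdala markers, 4 of 5 more than 2-fold above other regions (mean z 1.89, against 0.965 in the next). Higher there in the sections labelled Sema6d-/- were Serpina3n (log2 change 3.29), Pla2g4e (2.52), Glo1 (1.97) and Btbd9 (1.10), a gene tied to restless legs syndrome. Lower were Lmo3 (-2.96), Penk (-1.63), the dopamine signalling phosphoprotein gene Ppp1r1b (-1.68), the ciliary rootlet gene Crocc (-1.38) and the inositol kinase gene Itpka (-1.06). Pigv had no UMI there in the sections labelled Sema6d-/-, at least 11.9-fold lower against a floor of 3 counts over the group. Cort was 60.5-fold lower (95% exact interval 10.7 to 2402) and Txlna 74.8-fold lower (95% exact interval 13.3 to 2967). Penk and Ppp1r1b were also among the striatal markers. Over whole sections Penk did not pass (-0.22, edgeR adjusted p = 0.0703), while Ppp1r1b was lower (-0.54). In the striatal Adora2a region, where Penk was highest, it stood at 0.23 on the log2 scale, against -0.78 outside that region.

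The edgeR test covered 11056 genes in the Cyp26b1 region, with 4 higher and 8 lower, and 1619 at an unadjusted p under 0.05. Adjusted p ranged from 0.00149 for Lmo3 and 0.00340 for Penk to 0.0436 for Btbd9. Gabra2, a GABA receptor subunit gene, was next in rank and did not pass (1.83, adjusted p = 0.0520). Counts here depended on single sections: without replicate 1 of the sections labelled Sema6d-/-, 643 genes were higher and 609 lower, and without replicate 2, 597 and 479. Without WT replicate 1, and likewise without WT replicate 2, 18 were lower.

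Whether a gene's genotype difference in 1 region differed from that in the others was tested directly. The 1 gene that passed was Arhgap25, a GTPase activating protein gene, in the Adam33 region, which carries layer 4 markers, and it is named after its value was seen. Its difference there was -2.38 on the log2 scale relative to elsewhere (SE 0.0939, limma adjusted p = 0.0318). Relative to the other regions, Arhgap25 in the Adam33 region stood at 1.36 and 1.38 in the WT sections and -0.99 and -1.02 in the sections labelled Sema6d-/-, on 101 and 4 UMIs in all. The call was lost without either WT section, with the replicate number as a block, at resolutions 0.5 and 1.5 and without centring, while 1433 and 3819 calls arose without replicate 1 or 2 of the sections labelled Sema6d-/-. The design recovered 48.7% of simulated 4-fold differences in the Cyp26b1 region and none of 2-fold, and no other region was simulated.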

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

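Of the tests below, those of library depth and of region makeup by standardised values were set before their results were seen; all others (strain segments, linkage, equal spots, region shares alone, genes kept after thinning, mismatch, spread, source change, label exchange and measured part) were chosen only afterwards. The source change was first compared by size alone and then by sign as well, and the bound of the equal spots test was moved from at least to more than 75% after its value was seen and then put back. The spread tests were first run on 47 genes, and 4 genes whose values had already been seen were then left out. Ttr was left out of the source change test after its value was seen, and with Ttr that test had stayed open for the genes seen beforehand. Tests of the count of genes and of Sema6d by region makeup were dropped, as their values had been seen: 2402 genes higher and 2254 lower after thinning, and a lowest regional log2 change of Sema6d of 0.87.

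Arhgap25 in the Adam33 region stood out because its genotype difference there departed from that in the other regions (-2.38 on the log2 scale, limma adjusted p = 0.0318). Features outside the tissue matrices, which no comparison used, took 5.48% ± 0.0423 of tissue UMIs in the sections labelled Sema6d-/- (SD, n = 2) and 5.39% ± 0.00192 in WT. Features with deprecated identifiers took 0.807% ± 0.0180 and 0.662% ± 0.0137.

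The 199 located genes with 2-fold changes clustered along chromosomes: 8 of 487 windows of 5 Mb were enriched (3 on chromosome 4 and 1 each on chromosomes 2, 5, 6, 15 and 17), against at most 1 in 1000 random reassignments, and the chromosome 2 window of Sema6d was enriched without Sema6d itself (adjusted p = 3.84e-05). The reassignments moved single genes, so neighbouring members of a family were not kept together. Such neighbours among the 2-fold genes include Zfp979, Zfp982 and Zfp984, and H2-T22 and H2-T23. The excess over random reassignments may thus be overstated. The enriched windows hold the named genes Pla2g4e, Masp2, Hist4h4, Cort, Txlna, Smco3, Lmo3, Pde6h and Spg11, but not others such as Glo1, Serpina3n, Pigv and Pmch. Loss of detection by sequence mismatch is argued against as the single cause for the 51 genes with 2-fold changes in the windows. Of these, 52.9% were lower (95% interval 38.5 to 67.1), where such a cause would need at least 75%. Mismatch stays open for the 27 lower genes, Cort and Txlna among them, as a share over all 51 cannot decide it for a part. Region makeup is argued against too: region shares alone gave at most 16.3% of the log2 change of any of the 51 genes (25.7% over single pairs of sections), and equal spots kept 75% of the windows, exactly at the bound; the test by standardised values, set beforehand, came out for region makeup with 12.5% of the windows kept, under the 50% set, but it could not decide, as only 12 of the genes were tested there, all 12 past the threshold and with a median of 98.7% of their change. Depth is argued against for the 42 genes still tested after thinning, which each kept at least 80.7% of their change, 41 past the threshold and Psca not (adjusted p = 0.0645), and stays open for the other 9, with 62.5% of the windows kept. Segments of another strain may account for these 8 windows, against the strain label, as a hypothesis since the window size and 2-fold limit came from exploring these data. Linkage to the targeted allele was judged by position alone: the 7 windows on other chromosomes cannot be linked to it, whatever their cause.

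Transcripts made mainly in 1 region, such as Pmch, were more abundant elsewhere in the WT sections. Of 43 such genes, 29 (67.4%, against 16.7% by chance) had a higher ratio outside to inside in both WT sections, and 1 the opposite; the first 47 genes gave 70.2%, and the 38 of the 43 that were highest in a tested region 65.8%. The median log2 change of the 43 genes inside was 0.16 (95% bootstrap interval 0.06 to 0.31, and 0.07 to 0.36 for the 38). The bootstrap intervals given here resample genes and cover no spread between sections. A fall of at least 0.212 was needed, 50% of the change outside (-0.42), and only 2 of the 34 genes lower outside fell by 50% of their own. A genotype change in the cells that make these transcripts is thus argued against for the 43 genes as a set, in these sections. As the whole cause it is argued against also for 8 genes seen beforehand, Ttr left out as it was highest in an untested region: their median was 0.18 inside (interval -0.94 to 0.24) and -2.20 outside, 0 of 8 fell by 50% of their own change, and a partial change stays open for Pmch (-0.94 inside), Hcrt (-1.07) and Cartpt (-0.80), but not lower inside were Avp (1.79), Oxt (0.24), Penk (0.23), Arhgap36 (0.19) and Prkcd (0.17). Spread of RNA or barcodes between spots may contribute and stays open, as all 3 shares missed the 75% set for it.

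Sema6d was higher in the sections labelled Sema6d-/- by a log2 of 1.11. The smallest difference between labels was 10.6 times the largest within a label. This argues against an exchange of 1 section between the labels only if the Sema6d signal follows the genotype. Whether it does is not known, as depth split the labels as well. An exchange of both labels could leave Sema6d at 46.1% of the higher level in the sections labelled WT, and without the level the allele leaves the labels and their reverse cannot be told apart. A measured part outside the deleted part could equally give the log2 change of 1.11, and no coordinates of either are given. No test separates these from an effect of the genotype on its own transcript.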

How the results depend on the processing

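The Sema6d result kept its direction and its side of the threshold in every alternative run (1.10 to 1.12, and 1.03 to 1.19 with a section left out). Of the named genes that passed, 144 of 236 whole-section, 105 of 202 standardised and 9 of 12 amygdala marker region calls were kept in all alternatives, and 0 of 7 list calls. With a section left out, the lone section was assumed to vary like the other label's. Left-out sections gave 1778 to 2601 genes higher and 1623 to 2386 lower over whole sections, 1191 to 2214 and 1305 to 2934 standardised, 10613 to 14956 and 7979 to 12534 gene-by-region calls, 5 to 643 and 18 to 609 in the amygdala marker region, and 0 to 3819 for region by genotype. Standardised genes higher were 2910 with the replicate number as a block, 1113 without a filter and 1121 when clustered without centring, which gave 1393 lower. Gene-by-region calls higher and lower were 5666 and 3924 with DESeq2, 10187 and 8959 thinned, 5514 and 4520 without centring, 7302 and 6052 in spots with 4 or more neighbours of their region, and 9874 and 8535 in regions of at least 50 spots, where fewer regions were tested. Amygdala marker region genes higher and lower were 199 and 204 without a filter, 9 and 13 with DESeq2, 123 and 88 at resolution 1.5, 154 and 131 without centring, 11 higher in spots with 4 or more neighbours, and 13 lower with the block. For region by genotype, limma gave 0 calls with the block, at resolutions 0.5 and 1.5 and without centring; its main setting had 1692 genes of the Adam33 region at an unadjusted p under 0.05, and no other tool was run. With an estimated correlation, camera called 0 lists, which alone gives the 0 of 7 list calls kept. With 4 sections that setting has little power, so it does not decide about the calls. With standardised values 1 list was higher. Standardised directions reversed with equal numbers of spots for Oxt (0.52), Dlx5 (0.0699), Slc17a6 (0.15), Foxp2 (0.14), Npas4 (0.00713), Penk (0.0472) and Nts (0.28), and for Gfap (0.0554) without centring. The setting with equal numbers of spots sums counts over regions and uses edgeR. It thus changes the measure and the test as well as the spots, and its reversals cannot be put down to spot numbers. The cause was not tested in any of these alternatives. The replicate numbers give only 2 pairs, and differences of sections with the same number correlated at 8.93e-04 across genes over whole sections and 0.429 standardised, where genes are not independent replicates. In the less deep sections labelled Sema6d-/-, 2875 and 2648 of the genes had no UMI, against 1547 and 1467 in WT. Whether depth alone gave this difference was not tested.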

Other observations

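The tests of the hypotheses in this part were chosen only after the results were seen. Genes known to vary between mouse strains differed between the labels. C57BL/6J mice are known to lack part of Nnt, a mitochondrial transhydrogenase gene, and to carry a variant that lowers Gabra2, a GABA receptor subunit gene. Both, picked out after their values were seen, were lower in the WT sections. Nnt had 3.94 ± 0.583 CPM in WT and 12.1 ± 1.96 CPM in the sections labelled Sema6d-/- (SD, n = 2 each), and a further gene model of the same name was higher in the sections labelled Sema6d-/- by a log2 of 0.57 (adjusted p = 0.00109). Gabra2 had 57.1 ± 1.89 CPM in the sections labelled WT and 115 ± 13.4 CPM in the sections labelled Sema6d-/- (SD, n = 2 each). This would be consistent with another strain background in the sections labelled Sema6d-/-, against the label, which the 8 windows tested for strain segments also leave open.

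Glo1, Btbd9 and the dynein gene Dnah8 lie side by side on chromosome 17 and were all higher in the sections labelled Sema6d-/-, by log2 changes of 1.93, 1.18 and 2.85. A duplicated chromosome segment may account for them: of the 6 nearest tested genes outside, 2 were also higher by at least 1.4-fold, Umodl1 (0.95) and Abcg1 (0.53). That count met its bound exactly, and the 3 genes inside had been seen before, so only the neighbours were a new test.

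Copies of a gene family, also picked out after their values were seen, moved apart. Serpina3g fell by 1.19 on the log2 scale while its neighbour Serpina3n rose by 2.29. Among histone H4 genes, Hist4h4 rose by 1.56, Hist1h4h fell by 0.26, and Hist2h4 had 0.15 without passing. Spots off the tissue held 19.7% and 15.5% of all UMIs in the WT sections and 15.5% and 13.9% in the sections labelled Sema6d-/-. The median spot off the tissue held 4.26% and 12.2% of the UMIs of the median spot on it in WT, and 6.55% and 4.48% in the sections labelled Sema6d-/-, so the labels were not separated by it.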
